A study of Mus musculus with 6 samples.

How the data were processed

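Total RNA of tail epidermis, separated from the dermis with EDTA, was amplified to cDNA, labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. The 3 young samples came from mice of 8 weeks, aged replicate 1 from a mouse of 22 months and aged replicates 2 and 3 from mice of 25 months. The labels give strain, genotype, age and number, but not sex, and do not say whether each sample came from a separate animal, so p-values measure the spread between these samples.

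The arrays were scanned and read with Feature Extraction 11.5.1.1, per the file headers, which give 1 slide and 1 scan. The deposited processed signal is a spot intensity on a linear scale, background-subtracted and detrended within each array but not scaled between arrays, per the file headers. The deposited median signals of spot and local background are raw intensity values, per the file headers. The scanner's flags for detection, saturation and spot outliers were also used. The authors' table of processed values holds log2 values of 33870 probes. Set against the scanner files, these matched the log2 intensity minus the array's 75th percentile, centred on each probe's median over the 6 arrays, with a correlation of at least 0.9999 for each array. Column medians were -0.01 for young replicate 1, -0.02 for young replicates 2 and 3, -0.01 for aged replicate 1, 0.02 for aged replicate 2 and 0.07 for aged replicate 3. All 33870 listed probes were well above background on at least 1 array, as were 4 probes that the table does not list.

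Values were taken as log2 of the processed signal minus the array's 75th percentile of it. Control spots and spots marked as outliers by the scanner software, 116 to 170 per array, were left out, and spots of a probe were averaged. Probes were named through their RefSeq accession with a table of the GRCm38.p6 assembly. Of 55681 probes 28331 matched, for 21368 genes, and 27350 stayed unnamed. Col17a1 was named in this way. No coordinates are given, since the files use the mm9 build. A probe was tested where it was well above background on at least 3 of the 6 arrays, whichever they were, which 29508 probes met. A gene with several such probes was represented by the brightest, which left 14135 genes and 10931 unnamed probes, 25066 features in all. A second probe of Cdkn2a and of Limch1 was well above background on 0 arrays, and a second probe of Rgs7bp differed by 2.74 log2 units.

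Aged and young arrays were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, no covariate). Benjamini-Hochberg adjustment ran over all features, with a threshold of 0.05. Differences are aged minus young on the log2 scale. Where a probe was not well above background on any array of a group, "at least" gives a bound: the brighter group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. With 3 arrays against 3, an exact permutation test of a single value cannot give a p under 0.1, so none is given. A looser count took genes at an unadjusted p under 0.05 and at least 2-fold.

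Before the data were examined, 34 gene lists for keratinocyte biology, skin appendages and other cell types of skin were fixed, beside a sex-linked list used as a check only. The 33 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move, on balance, one way without comparing them with other genes, stood beside it. Members were also adjusted over the list alone. A list's deviation on an array is the median over its genes of the value minus the young mean.

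The genes named were also fixed by a rule in advance. It took a panel of 8 genes (Col17a1, Itga6, Itgb4, Krt5, Krt14, Krt15, Krt10 and Cdkn2a). It then took in each direction the 10 genes with the largest difference among those past the threshold, well above background on all arrays and without overlap of the groups. Places left were filled in order of unadjusted p from genes of at least 2-fold difference. The filling was read as asking also for detection on all arrays and for no overlap. It took up to 5 genes per direction detected in 1 group only, and up to 4 members of each list by unadjusted p. Genes named outside the rule are given as chosen after their values were seen; this holds too for Col1a1 and Rgs7bp, which passed the threshold without detection on all arrays.

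The titles give both groups the replicate numbers 1 to 3. Deviations of same-numbered samples from their group means correlated across features with r of 0.414, 0.259 and 0.102, but the labels name nothing that the numbers share. Deviations cancel out within a group, so a likeness of the samples numbered 1 alone favours positive values among the others. These correlations therefore cannot decide whether the numbers pair the samples. Genes are not independent replicates in such a correlation. Young replicate 3 correlated less with aged replicate 3 than young replicate 2 did (0.286). The reported fit does not use the numbers, and the fit with the replicate number as a block is an alternative.

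The other settings fixed before the data were examined were quantile normalization, scaling to the array median, no filter and a filter on all 6 arrays, the mean of a gene's probes, an intensity trend with robust variance, array weights, the replicate block, the authors' processed values, other list tests, and leaving out each array. A normexp correction was planned on the mean signal, which the files used here do not hold, and was run on the median signal with an offset of 50. That change, a block and an omission for the 2 arrays with Y-linked transcripts of Ddx3y and Eif2s3y, and a block for the row of the array on the slide were chosen after seeing the data. Row 1 held young replicates 1 and 2 and row 2 the other 4 arrays, so with the row as a block the groups are compared through the 3 aged arrays and young replicate 3 alone.

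The fit was tested on simulated data for aged against young, in 10 runs with 200 of 25066 features changed. It called 39.4% of features changed 2-fold, 87.8% of those changed 4-fold and 93.8% of those changed 8-fold, all with the right sign, and 5.46% of its calls were false. The simulated noise was independent between genes and equal in both groups. On the real arrays the median SD of a gene was 0.145 in young and 0.211 in aged, so these rates need not hold for the real fit. With 5 lists shifted by 0.5 log2 units, camera called 88% of them with the preset correlation and 70% with an estimated one. With no list changed but a deviation shared by a list's genes on each array (SD 0.3 log2 units), the preset correlation called 15.4 of 33 lists on average and the estimated correlation 0, so calls with the preset correlation are open to such shared deviations. Figures were drawn with matplotlib 3.10.9.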

Results

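Gene expression was measured in the epidermis of mouse tail skin from young and aged wild-type C57BL/6 mice, with 3 samples in each group. The young samples came from mice of 8 weeks. Aged replicate 1 came from a mouse of 22 months, and aged replicates 2 and 3 from mice of 25 months. Each sample was hybridised to its own 1-colour array, and the 75th percentile of its signal lay between 230.2 and 300.3 units. Between 50.02% and 54.38% of the 55681 probes were well above background on an array, and no spot was saturated. The number of arrays limits the precision of every value below. The comparison asked which genes differ between aged and young tail epidermis. Collagen XVII, the hemidesmosome protein that the series concerns, was measured by 1 probe and is given with the panel of basal and suprabasal genes.

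In aged epidermis 11 of 14135 tested genes passed the threshold, 6 higher and 5 lower than in young epidermis. The transcript of Cdkn2a, which encodes cell cycle inhibitors associated with cellular senescence, was well above background on 3 of 3 aged arrays and 0 of 3 young arrays, and was at least 5.98-fold higher in aged epidermis (limma adjusted p = 0.0354). Amhr2, the receptor of anti-Müllerian hormone, rose by 3.03 ± 0.13 on the log2 scale (SE, n = 3 arrays per group, 8.18-fold, limma adjusted p = 0.00756), and Mesp2, a transcription factor gene of somite segmentation, by 1.45 ± 0.10 (2.73-fold, adjusted p = 0.0283). The collagen genes Col1a1 and Col3a1 were lower. Col1a1 fell by 2.95 ± 0.18 on the log2 scale (7.72-fold, limma adjusted p = 0.0283). It was well above background on 3 young and 2 aged arrays, and its aged signals of -4.34 to -4.56 lay near the lower limit of detection, so the size of its fold is uncertain. Col3a1, not well above background on any aged array, was at least 5.14-fold lower (adjusted p = 0.0467). Chac1, which encodes an enzyme that degrades glutathione, fell by 1.79 ± 0.13 (3.46-fold, adjusted p = 0.0283).

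The remaining genes past the threshold also lay near the lower limit of detection. Rgs7bp was 3.31 ± 0.25 log2 units higher in aged epidermis (limma adjusted p = 0.0283) and well above background on 3 aged arrays and 1 young array. The homeobox genes Isl2 and Dlx6 were at least 2.70-fold and at least 2.16-fold higher in aged epidermis, with adjusted p = 0.0283 and 0.0467. Limch1 and Slco5a1, the latter a solute carrier gene, were at least 2.05-fold and at least 1.61-fold lower (adjusted p = 0.0283 for each). For all 11 genes the 3 aged values lay outside the range of the 3 young values. A further 5 probes without a gene name passed, 1 higher and 4 lower. Without aged replicate 1 the count was 809 genes, 277 higher and 532 lower, among them all 11. Without any other single array it was 0, with 1321 to 2411 genes at an unadjusted p under 0.05, and with the replicate number as a block it was also 0, with 2710. Replicate 1 of both groups carried transcripts of the Y-linked genes Ddx3y and Eif2s3y. Without these arrays 215 genes passed, 64 higher and 151 lower, again with all 11 among them. With aged replicate 1 alone left out, only young replicate 1 carried these transcripts, so that fit was not balanced for them. It also lacked the only aged mouse of a different age in months and the spread that this array adds to the aged group. All values below without aged replicate 1 alone share these limits.

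**Figure D1:**
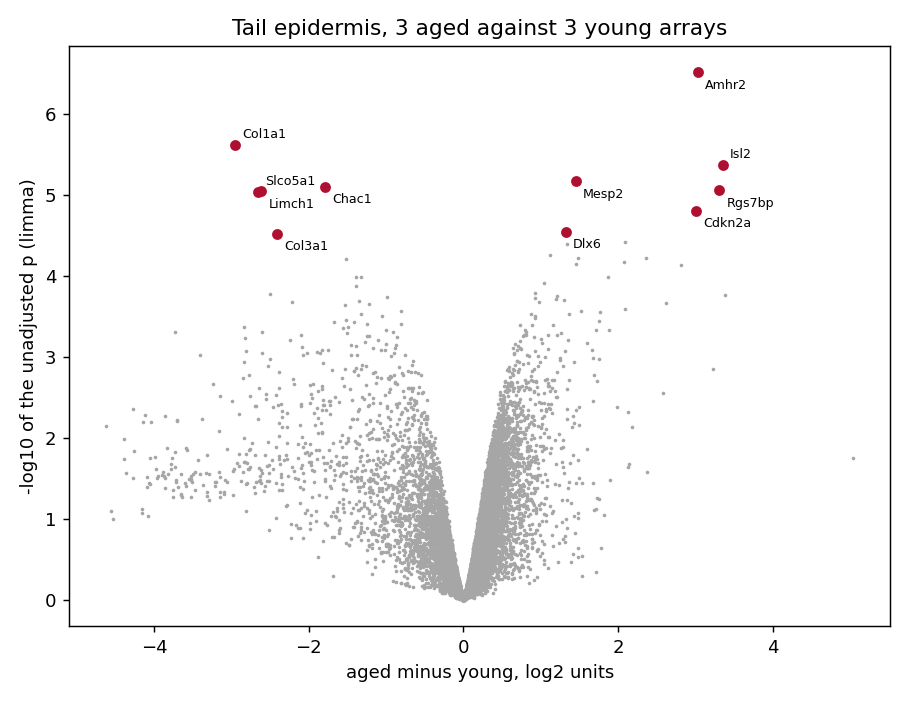
Each point is 1 of 14135 genes; the horizontal axis gives the aged minus young difference in log2 units and the vertical axis the -log10 of limma's unadjusted p. The 11 genes past the adjusted threshold are drawn in red, and points to the left of the centre reach larger differences than most points to the right.

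The looser count, at an unadjusted p under 0.05 and at least 2-fold, held 577 genes, 135 higher and 442 lower in aged epidermis, with no control of the false discovery rate. At an unadjusted p under 0.05 and any fold the balance was the other way, with 2498 genes, 1607 higher and 891 lower. Aged and young values did not overlap for 3813 genes, or 27.0% of those tested, where chance gives 10% on average. Genes on the same arrays vary together, so a single grouping can lie far from that average. The share was not counted for other groupings. Among genes well above background on every array, those next in order of p that missed the threshold were, on the higher side, Slc16a3 (a monocarboxylate transporter, 4.25-fold), Prkcb (a protein kinase C, 2.54-fold), Pcdhb16 (2.17-fold), Arhgef16 (2.79-fold), Star (a cholesterol transport protein of steroid synthesis, 2.75-fold), Akr1c13 (7.02-fold), Sncg (3.65-fold) and Ehbp1l1 (2.05-fold). Their limma adjusted p lay between 0.0552 and 0.0770. On the lower side they were Srgn (2.63-fold), Qpct (2.63-fold), the hair keratin-associated genes Krtap22-2 (2.55-fold) and Krtap19-5 (3.20-fold), the hair keratin gene Krt39 (2.50-fold), Fndc5 (2.90-fold), Fndc4 (2.67-fold), Ccdc68 (2.07-fold) and Sqor (2.87-fold), with adjusted p between 0.0703 and 0.0954.

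None of the panel genes of the basal layer and its anchorage passed the threshold. Col17a1 had a log2 signal of 5.64 ± 0.14 in young and 5.90 ± 0.27 in aged epidermis (SD, n = 3 arrays each), a difference of 0.26 ± 0.17 (SE, limma adjusted p = 0.441), so a fall of Col17a1 transcript was not detected. The integrin genes that pair in the hemidesmosome differed by 0.37 ± 0.21 for Itga6 (adjusted p = 0.381) and 0.59 ± 0.20 for Itgb4 (adjusted p = 0.218). When each array was left out in turn, Col17a1 differed by 0.13 (without aged replicate 3) to 0.40 (without aged replicate 1, adjusted p = 0.198) and Itga6 by 0.21 to 0.58 (adjusted p = 0.0663) for the same arrays. Itgb4 differed by 0.48 to 0.79 ± 0.13, and its value without aged replicate 1 passed the threshold, with an adjusted p of 0.0316. The basal keratin genes Krt5 and Krt14 differed by 0.12 ± 0.11 and 0.26 ± 0.13, and Krt15, a keratin of basal and bulge cells, by -0.30 ± 0.28, with adjusted p of 0.557, 0.336 and 0.593. Krt15 differed by -0.62 without aged replicate 1 (adjusted p = 0.0629) and by -0.086 without aged replicate 3. Krt10, a keratin of suprabasal cells, differed by 0.02 ± 0.11 (adjusted p = 0.950), and its sign changed with the slide row as a block (-0.06).

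**Figure D2:**
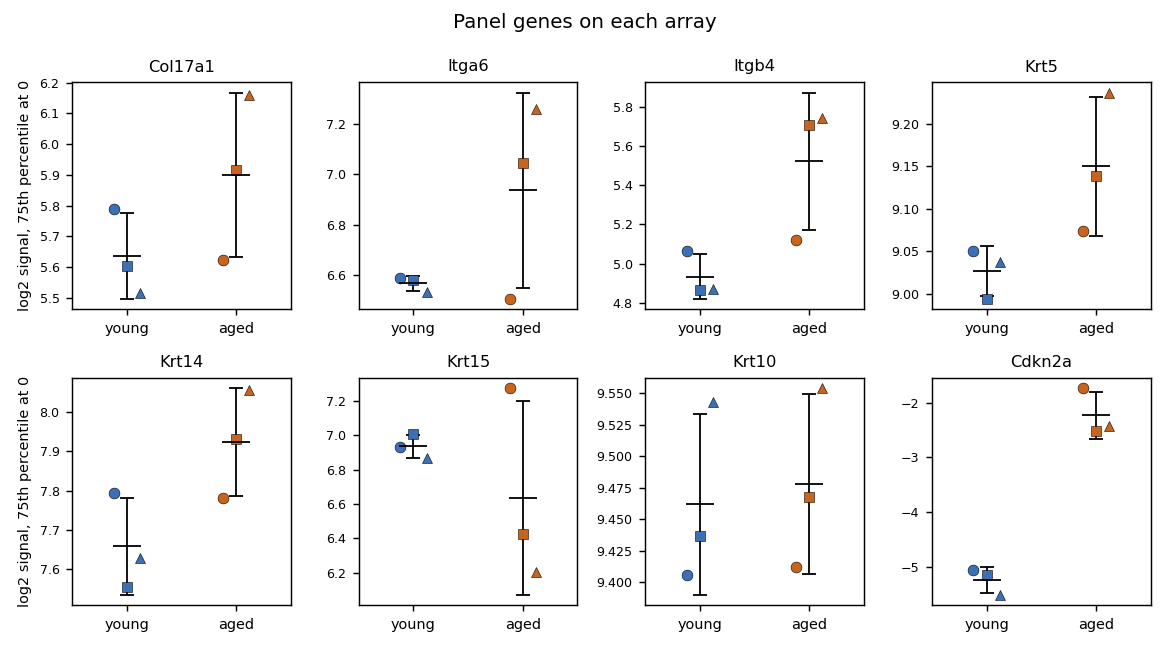
Log2 signal of the 8 panel genes on each array, with the array's 75th percentile at 0; circles, squares and triangles are replicates 1, 2 and 3, and the bars give the mean and SD of each group. Young and aged values lie apart for Cdkn2a, which is well above background on 0 of 3 young arrays, while the Col17a1 and Krt10 values of the groups overlap.

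Genes of the hair shaft and inner root sheath fell together in aged epidermis. All 26 tested members of this list were lower, by a mean of 2.70 log2 units (camera with its preset correlation, adjusted p = 5.85e-11, and adjusted p = 0.596 with an estimated correlation). No member passed the threshold singly, either over all genes or adjusted over the list alone, and 19 had an unadjusted p under 0.05. Examples were Krt72, an inner root sheath keratin (-2.90 ± 0.68 log2, SE), Padi3, a protein deiminase of the hair (-4.06 ± 1.26), the hair keratin Krt81 (-2.76 ± 0.92) and Krtap8-1 (-1.42 ± 0.35), with limma adjusted p of 0.149, 0.205, 0.217 and 0.153. The median deviation of the list from the young mean was -0.74 log2 units on aged replicate 1, -3.05 on aged replicate 2 and -5.88 on aged replicate 3, against -0.35 to 0.24 on the young arrays. Without aged replicate 1 the list's mean was -3.67, and 15 members passed over all genes and 22 adjusted over the list alone. Without aged replicate 3 the mean was -1.75.

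Pigment cell genes were lower on the same arrays. The 13 tested melanocyte genes were all lower in aged epidermis, and the list fell by a mean of 1.26 log2 units (camera adjusted p = 1.67e-05, and adjusted p = 0.596 with an estimated correlation). Mitf, the transcription factor of the melanocyte lineage, differed by -1.06 ± 0.17 (limma adjusted p = 0.107) and was the 1 member past the threshold adjusted over the list alone, with 0 over all genes. The receptor gene Kit differed by -2.10 ± 0.70, Tyrp1, an enzyme gene of melanin synthesis, by -1.59 ± 0.56, and Mlana by -1.93 ± 0.72. Aged replicate 1 had a median deviation of 0.00 and aged replicates 2 and 3 of -2.03 and -1.80, and without aged replicate 1 11 of the 13 genes were lower past the threshold. The tail scale list, of 4 keratin genes, held Krt35 and Krt31 with differences of -3.95 ± 1.40 and -3.37 ± 1.28, beside Krt36 and Krt84 with -0.05 ± 0.16 and -0.02 ± 0.14, whose sign turned under quantile normalization and under scaling to the median. Its mean of -1.84 did not pass (camera adjusted p = 0.214). It was -2.57 without aged replicate 1, with adjusted p = 0.0452 and, with an estimated correlation, adjusted p = 0.314.

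**Figure D3:**
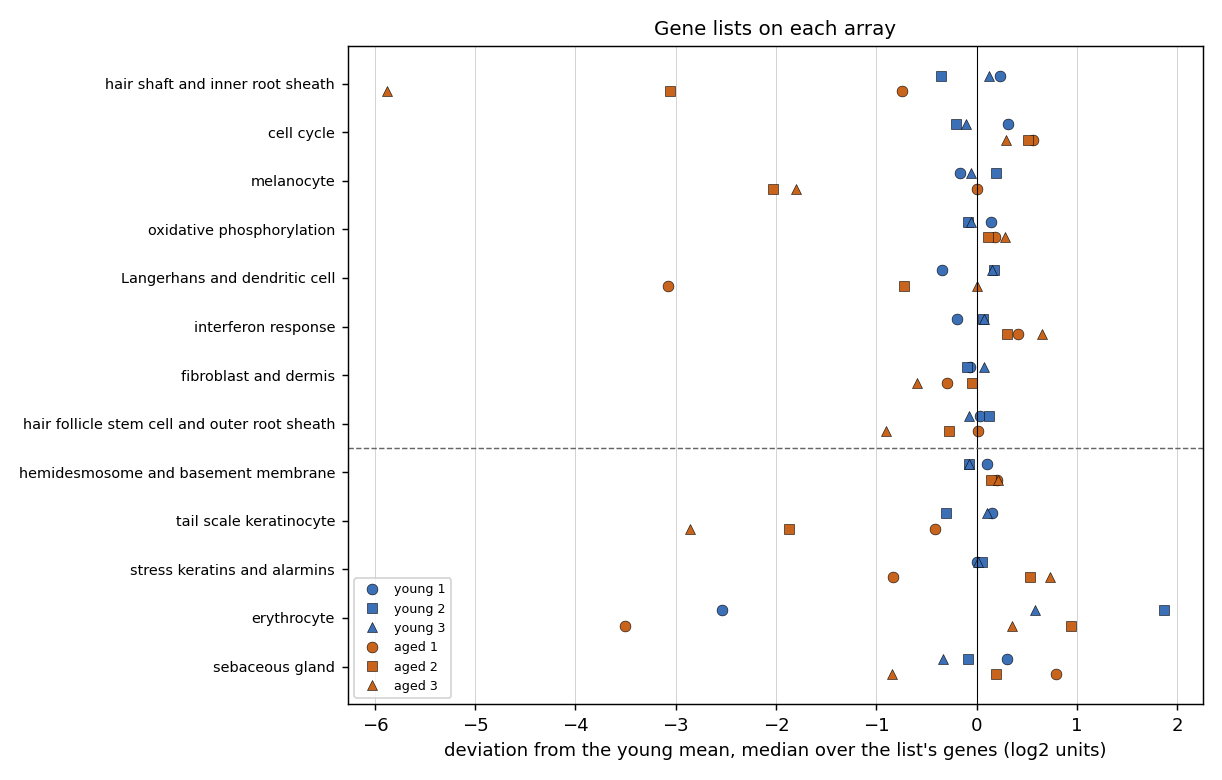
Each point is the median over a list's genes of 1 array's deviation from the young mean, in log2 units; the 8 lists above the dashed line passed the camera threshold with the preset correlation and the 5 below it did not. The hair shaft list reads -0.74, -3.05 and -5.88 on the aged arrays, and the erythrocyte list is low on replicate 1 of both groups.

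Cell cycle genes rose by a smaller amount. All 33 tested members were higher in aged epidermis, by a mean of 0.48 log2 units (camera adjusted p = 1.57e-09, and adjusted p = 0.596 with an estimated correlation). Over all genes 0 members passed, 2 passed adjusted over the list alone, and 15 had an unadjusted p under 0.05. Aurka and Plk1, kinases of mitosis, differed by 0.72 ± 0.13 and 0.57 ± 0.15, Prc1, a gene of the mitotic spindle midzone, by 0.83 ± 0.15, and Cdk1 by 0.65 ± 0.18, with limma adjusted p between 0.114 and 0.184. The list's median deviation was 0.56, 0.52 and 0.30 on aged replicates 1, 2 and 3, each above that of the same-numbered young array (0.32, -0.20 and -0.10), though aged replicate 3 lay below young replicate 1. Interferon response genes rose as a list, with 12 of 14 members higher and a mean of 0.41 (camera adjusted p = 0.0111, and adjusted p = 0.596 with an estimated correlation). The antigen processing genes Tap1 (0.74 ± 0.12), Psmb8 (0.81 ± 0.19) and Psmb9 (1.24 ± 0.33) led this list, and 3 members passed adjusted over the list alone and 0 over all genes. The camera call was lost without young replicate 1 (mean 0.32, adjusted p = 0.0842), without aged replicate 3 (mean 0.32, adjusted p = 0.0508), with array weights (mean 0.38, adjusted p = 0.0622) and with the slide row as a block (mean 0.30, adjusted p = 0.106), which rests on 1 young array.

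Oxidative phosphorylation genes rose by a mean of 0.18 log2 units, with 32 of 34 members higher (camera adjusted p = 0.00149, and adjusted p = 0.835 with an estimated correlation). Examples were Cox4i1 (0.35 ± 0.12), Ndufa2 (0.32 ± 0.11) and Sdhd (0.33 ± 0.12). The list's median deviation was 0.19, 0.12 and 0.29 on aged replicates 1, 2 and 3. On the same-numbered young arrays it was 0.15, -0.08 and -0.06, so aged replicate 2 lay below young replicate 1. No member passed over all genes or adjusted over the list alone, and under quantile normalization the mean was 0.08 with a camera adjusted p of 0.155. The median difference of all tested genes was 0.09 log2 units.

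Langerhans and dendritic cell genes fell as a list by a mean of 1.08 log2 units, with 14 of 16 members lower (camera adjusted p = 0.00708, and adjusted p = 0.721 with an estimated correlation). The median deviation was -3.07 on aged replicate 1, -0.72 on aged replicate 2 and 0.00 on aged replicate 3, and without aged replicate 1 the mean was -0.34 (camera adjusted p = 0.0412, and adjusted p = 0.699 with an estimated correlation). Without aged replicate 3 it was -1.63. Among the members with the smallest p, the Fc receptor chain gene Fcer1g differed by -0.73 ± 0.18 and the receptor gene Csf1r by -0.66 ± 0.28, while the lysosomal gene Cd68 was 0.62 ± 0.17 higher. No member passed over all genes or adjusted over the list alone, and with the filter for probes above background on all 6 arrays the list had a camera adjusted p of 0.0626.

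The fibroblast and dermis list fell by a mean of 0.64 log2 units (camera adjusted p = 0.0208, and adjusted p = 0.596 with an estimated correlation), while its median was 0.03, so mean and median differed in sign. Of 15 members, 2 were lower past the threshold over all genes, Col1a1 and Col3a1, and 5 adjusted over the list alone. Col1a2 differed by -2.08 ± 0.35 and the surface peptidase gene Dpp4 by -0.97 ± 0.25. The call was lost with the replicate block (adjusted p = 0.0608), array weights (adjusted p = 0.184), normexp (mean -0.16, adjusted p = 0.0527) and the filter for all 6 arrays (mean -0.16, adjusted p = 0.503), and without young replicate 1 (adjusted p = 0.0642) or aged replicate 3 (adjusted p = 0.228). Hair follicle stem cell and outer root sheath genes fell by a mean of 0.37, with 16 of 20 members lower (camera adjusted p = 0.0420, and adjusted p = 0.640 with an estimated correlation) and none past the threshold over all genes or adjusted over the list alone. Lgr5 differed by -1.67 ± 0.57, Tbx1 by -0.90 ± 0.40 and Cd34 by -0.68 ± 0.31. The call was lost with array weights (mean -0.27, adjusted p = 0.0900) and the slide row as a block (mean -0.27, adjusted p = 0.194), and without young replicate 1 (mean -0.35, adjusted p = 0.105), young replicate 2 (mean -0.34, adjusted p = 0.0701) or aged replicate 3 (mean -0.13, adjusted p = 0.364), and without aged replicate 1 the mean was -0.57.

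The other lists of keratinocyte biology did not pass with all 6 arrays. Of 22 hemidesmosome and basement membrane genes 14 were higher, with a mean of 0.05 and a median of 0.26 (camera adjusted p = 0.328). Plec and Lama3 differed by 0.35 ± 0.11 and 0.59 ± 0.20. The basal keratinocyte list had a mean of 0.12 (adjusted p = 0.369), with Igfbp2 at 1.00 ± 0.25, Bcam at 0.46 ± 0.13, Ly6a at 0.73 ± 0.25 and Sostdc1 at -0.73 ± 0.24. The suprabasal and cornified envelope list had a mean of -0.08 (adjusted p = 0.426), with Rptn at -1.17 ± 0.42, or -0.71 without aged replicate 1. Desmosome and cell junction genes had a mean of -0.07 and a median of 0.08 (adjusted p = 0.873), with Dsc2 at -1.10 ± 0.30. Cell polarity and spindle orientation genes had a mean of 0.00 (adjusted p = 0.926). The polarity kinase gene Prkcz, at -1.24 ± 0.18, passed adjusted over that list alone but not over all genes (limma adjusted p = 0.0979), and Pard6a was at 0.43 ± 0.13. Barrier lipid synthesis genes had a mean of 0.08 (adjusted p = 0.328), with the sterol synthesis genes Sqle and Hmgcs1 at 0.44 ± 0.13 and 0.43 ± 0.14. This mean was 0.20 without aged replicate 1 (camera adjusted p = 0.0445, and adjusted p = 0.489 with an estimated correlation).

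Among lists of stress, signalling and repair, senescence and secretory factors had a mean of 0.27 (camera adjusted p = 0.426). Cdkn2a was the 1 member past the threshold over all genes and 2 passed adjusted over the list alone, with Plau at 0.87 ± 0.22. The p53 targets had a mean of 0.18 (adjusted p = 0.275), with Bbc3 at 0.74 ± 0.18 and Ccng1 at 0.38 ± 0.13. Proteases that cleave collagen XVII and their inhibitors had a mean of 0.25 (adjusted p = 0.257), with Mmp2 at 0.81 ± 0.21 and Adam8 at 0.92 ± 0.33. Notch and Wnt genes had a mean of -0.42 (adjusted p = 0.101), with Wnt5a at -0.91 ± 0.24, Nkd1 at -2.03 ± 0.61 and Jag2 at 0.45 ± 0.12. Mesenchymal transition genes had a mean of -0.24 with an upward camera direction (adjusted p = 0.926), Tgfbi at 0.66 ± 0.11 and Fn1 at -2.61 ± 0.90, and 1 passed adjusted over the list alone. Inflammatory cytokines and receptors had a mean of 0.11 (adjusted p = 0.699), with Il33 at 0.75 ± 0.25. Antioxidant genes had a mean of 0.09 (adjusted p = 0.539), with Txnrd1 at -0.62 ± 0.13. Circadian clock genes had a mean of 0.23 (adjusted p = 0.142), with Arntl at 0.56 ± 0.11, Nr1d1 at 0.74 ± 0.19 and 1 member past the threshold adjusted over the list alone. Immediate early and heat shock genes had a mean of 0.34 (adjusted p = 0.248), with Dnajb1 at 0.53 ± 0.24. Senescence factors had a mean of 0.44 without aged replicate 1 (camera adjusted p = 0.113) and 0.076 without aged replicate 2. Mesenchymal transition genes had a mean of -0.58 without aged replicate 1 (camera adjusted p = 0.221) and -0.013 without aged replicate 3. Of these lists 4 passed once aged replicate 1 was left out, when the mean was -0.57 for Notch and Wnt genes, 0.83 for immediate early and heat shock genes, 0.28 for clock genes and 0.34 for inflammatory genes. Their camera adjusted p were then 0.0171, 4.63e-08, 0.0445 and 0.0445, with an adjusted p of 0.314 for each with an estimated correlation. With aged replicate 1 kept, Notch and Wnt genes passed with the array median, no filter, normexp and the Y-linked block (camera adjusted p from 0.0140 to 0.0496, and adjusted p from 0.547 to 0.609 with an estimated correlation). Immediate early and heat shock genes passed with array weights and the Y-linked block, and an estimated correlation passed 0 lists under each of these settings.

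The stress keratin and alarmin list had a mean of 0.34 and a median of 0.08 with a downward camera direction (adjusted p = 0.926). Krt6a differed by -1.01 ± 0.21 and Lcn2 by 2.13 ± 0.50 (limma adjusted p = 0.131 and 0.146). On single arrays the list's median deviation was -0.83 on aged replicate 1 and 0.53 and 0.74 on the other aged arrays. S100a8 and S100a9, alarmin genes chosen here after their values were seen, had log2 signals of -1.82 and -1.11 on aged replicate 1, against 6.48 and 7.17 on aged replicate 2, 5.89 and 6.73 on aged replicate 3, with young means of 1.80 and 2.73. Without aged replicate 1 the list's mean was 0.99 (camera adjusted p = 0.000189, and adjusted p = 0.308 with an estimated correlation), with 7 members higher and 1 lower past the threshold over all genes.

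**Figure D4:**
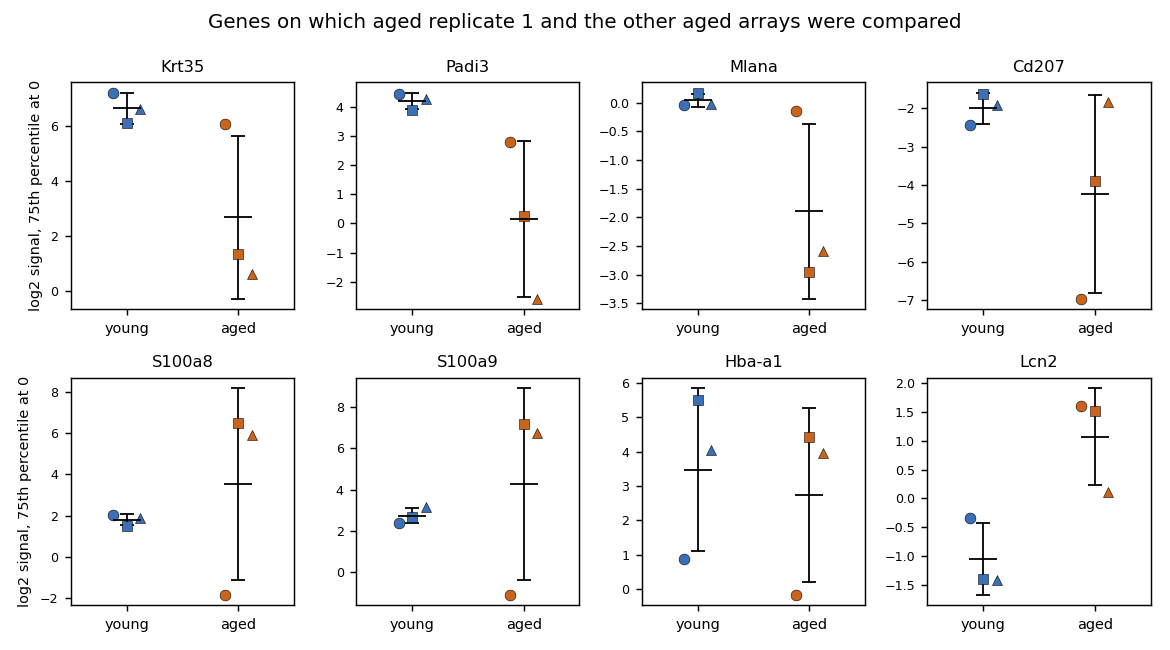
Log2 signal of 8 genes on each array, with the array's 75th percentile at 0; circles, squares and triangles are replicates 1, 2 and 3, and the bars give the mean and SD of each group. S100a8 reads -1.82 on aged replicate 1 and 6.48 and 5.89 on the other aged arrays, and Hba-a1 reads 0.87 and -0.16 on replicate 1 of the young and aged groups.

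Markers of other cell types gave no further list past the threshold. T cell genes had a mean of 0.00 and a median of -0.04 with a downward camera direction (adjusted p = 0.873), with Thy1 at 1.60 ± 0.47 and Cd5 at 0.27 ± 0.10, and 10 of 26 were tested. Neutrophil and mast cell genes had a mean of -0.25 (adjusted p = 0.326), with Cxcr2 at 0.93 ± 0.37. Endothelial and pericyte genes had a mean of -0.26 (adjusted p = 0.248), with Eng at -0.96 ± 0.20, the 1 member past the threshold adjusted over the list alone. Skeletal muscle genes had a mean of 0.04 (adjusted p = 0.855), with Tnni2 at 0.36 ± 0.12. Adipocyte genes had a mean of -0.19 with an upward camera direction (adjusted p = 0.855) and Fabp4 at -3.15 ± 0.83. Sebaceous gland genes had a mean of -0.11 and a median of 0.10 (adjusted p = 0.873), with Awat2 at least 1.72-fold lower (limma adjusted p = 0.139) and Acsbg1 at 0.38 ± 0.10. Merkel cell and nerve genes had a mean of -0.29 (adjusted p = 0.256), with Krt18 at -1.56 ± 0.67, and a mean of -0.48 without aged replicate 1 (adjusted p = 0.0722) and -0.11 without aged replicate 3. The adipocyte, neutrophil and mast cell, and sebaceous means were -0.42, -0.14 and -0.46 without aged replicate 1, and none of these passed. Of 12 B and plasma cell genes 2 were measured, too few for a test. Erythrocyte genes had a mean of -0.79 (adjusted p = 0.306), with Slc4a1 at -1.80 ± 0.61, and with the replicate block the same mean had a camera adjusted p of 0.000796, and an adjusted p of 0.703 with an estimated correlation. Their median deviation was -2.54 on young replicate 1 and -3.50 on aged replicate 1, against 0.35 to 1.87 on the other 4 arrays, and the mean was -1.78 without young replicate 1 (camera adjusted p = 0.0498, and adjusted p = 0.474 with an estimated correlation) and 0.13 without aged replicate 1 (adjusted p = 0.754).

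In all, 8 of 33 lists passed camera with its preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.596, 1 list at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.092, 8 lists at an unadjusted p under 0.05). With the replicate block 8 lists passed, 7 of them shared with the fit without it, and without aged replicate 1 15 passed, with all 8 among them; with an estimated correlation 0 lists passed in either fit. Fry passed 16 lists without aged replicate 1, 11 without both arrays with Ddx3y and Eif2s3y transcripts and 1 without young replicate 1.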

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

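Each test in this part was chosen after the result was seen. Transcripts of Ddx3y and Eif2s3y, genes of the Y chromosome that no comparison used, were well above background on replicate 1 of each group and not on the other 4 arrays. Ddx3y lay 9.25 log2 units above the array's negative controls on young replicate 1 and 8.90 on aged replicate 1, and Eif2s3y 10.39 and 10.44. Kdm5d, likewise well above background on these arrays only, lay 3.39 and 2.29 above them. Uty was well above background on young replicate 3 too, where it lay 5.04 above the negative controls, against 3.45 on young replicate 1 and 4.48 on aged replicate 1. A second probe of Uty was well above background on replicate 1 of each group only, with a log2 signal of -6.83 on young replicate 3, so the Y-linked genes did not part the arrays in the same way with every probe. Xist, the transcript of the inactive X chromosome, had log2 signals of -2.87 on young replicate 1 and -7.07 on aged replicate 1, against 0.72 to 1.34 on the other 4 arrays, and was well above background on young replicate 1 but not on aged replicate 1. The labels used here give no sex. With 3 arrays in each group, no single array was tested for lying apart from its group.

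Aged replicate 1 stood apart from the other aged arrays: its correlation over features was 0.976 and 0.964 with aged replicates 2 and 3, while those correlated at 0.989. With young replicate 1, the other array with Ddx3y and Eif2s3y transcripts, it was 0.984, and with young replicates 2 and 3 it was 0.975 and 0.976. On aged replicate 1 54.07% of probes were above background, within the 50.02% to 54.38% of the other arrays, so no loss of detected probes was seen. RNA was amplified before hybridisation, so this share does not measure RNA yield or quality, which stay open. A wrong label on an array of a young mouse was examined over genes that part aged replicates 2 and 3 from 2 young arrays. Of these, 29.6%, 27.9% and 23.3% lay nearer the aged arrays on aged replicate 1, against 8.01%, 4.23% and 0.727% on the young array left out. The lowest gap of 21.6 points exceeds the range of the young arrays, so aged replicate 1 was unlike those 3 arrays. Any array with larger deviations could raise this share, so it cannot tell an aged mouse from an atypical young one. Earlier forms of this test left the question open too. Median positions from 0 (young) to 1 (aged) were 0.209 to 0.268 on aged replicate 1 and -0.0572 to 0.161 on the young arrays left out. The lowest gap of 0.107 lay under the range of 0.218 of the young arrays left out. For most of the genes so chosen, aged replicate 1 lay nearer the young arrays. The choice rested on the other aged arrays, which favours such a result, and it does not cover all tested genes. A difference between the sexes may contribute, with r = 0.409 across genes between the deviations of replicate 1 in the young and the aged group, but with 1 such array per group and the only mouse of 22 months among them, sex, age in months and the single animal cannot be told apart, and age stays an untested biological explanation.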

How the results depend on the processing

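The Y-linked, slide row and normexp alternatives were chosen after seeing the data. Of the values for 112 named genes under alternatives, 1795 kept direction and side of the threshold, 102 lost the call, 199 gained one and 18 changed sign. Only the 11 reported genes could lose a call, so most values that kept their side belong to genes that had not passed. For the 33 lists the numbers were 601, 33, 23 and 36. The mean of a gene's probes and the authors' values each gave 11 genes, all 11 shared with the reported ones. Genes past the threshold, with those higher and lower, were 7 (4 and 3, all among the 11) under quantile normalization, 21 (15 and 6) with the array median, against 11 (6 and 5) as reported, 1 (1 and 0) with no filter, 3 (2 and 1) with the filter on all 6 arrays, 18 (13 and 5, 8 of them shared) with intensity trend and robust variance, 4878 (3096 and 1782) with array weights, 15 (11 and 4, 3 of them shared) with normexp, 20 (12 and 8) with the Y-linked block and 215 (64 and 151) without both arrays with Y-linked transcripts. The replicate block gave 0 (0 and 0; limma, 2710 genes at an unadjusted p under 0.05) and the slide row as a block 0 (0 and 0; 858). Leaving out each array gave 0 to 809 genes, 0 to 277 higher and 0 to 532 lower, with 809 without aged replicate 1. The array weights came from an estimate that stopped before it converged, with weights of 11.8 for aged replicate 2 and 0.221 for aged replicate 1. The median difference of all genes was 0.09 as reported, 0.17 with the array median and 0.05 under quantile normalization. The looser count was 369 with the filter on all 6 arrays, 1017 with array weights, 260 with normexp, 952 without both arrays with Y-linked transcripts, 352 with the slide row as a block and 403 to 960 when each array was left out. The lists past the threshold numbered 14 without both arrays with Y-linked transcripts, 0 with an estimated correlation, 0 with fry and 5 to 15 when each array was left out. List calls lost were oxidative phosphorylation under quantile normalization, fibroblast with the replicate block, normexp, array weights and the filter on all 6 arrays, Langerhans with that filter, interferon and outer root sheath with the slide row block and array weights. Notch and Wnt genes gained a call under 6 alternatives. Fry passed 16 lists without aged replicate 1 and with array weights, 11 without both arrays with Y-linked transcripts, 2 with the Y-linked block and 1 with the array median and without young replicate 1, and an estimated correlation 0 under each. With the slide row as a block 1 young array stands against the 3 aged ones. Other than the settings with fewer arrays or fewer probes, the cause was not tested.

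Values of the following results changed sign. Under quantile normalization Krt36 was 0.070, Krt84 0.086, the hemidesmosome list -0.0030 and the polarity list -0.045. With the array median Krt36 was 0.028, Krt84 0.060, the suprabasal list 0.0011 and the desmosome list 0.0082. With no filter the polarity list was -0.0083, the endothelial list 0.080 and the adipocyte list 0.13. With the mean of a gene's probes the polarity list was -0.017 and the T cell list -0.12. With array weights Krt10 was -0.019, Krt84 0.025, Hba-a1 0.19 and the sebaceous list 0.044. With the slide row as a block Krt10 was -0.065, the T cell list -0.072, the muscle list -0.038 and the sebaceous list 0.16. The sebaceous list was 0.14 with the filter on all 6 arrays and 0.085 with normexp. Without both arrays with Y-linked transcripts Krt36 was 0.0092, Krt84 0.084 and the suprabasal list 0.083. When each array was left out, Krt10 ranged from -0.022 to 0.057, Krt36 from -0.16 to 0.061, Krt84 from -0.099 to 0.094 and Hba-a1 from -2.04 to 0.71. Among the lists the hemidesmosome mean ranged from -0.027 to 0.15, the suprabasal from -0.20 to 0.090, the stress keratin from -0.018 to 0.99, the polarity from -0.085 to 0.11, the inflammatory from -0.024 to 0.34, the barrier lipid from -0.018 to 0.20, the T cell from -0.12 to 0.14, the muscle from -0.0048 to 0.075, the adipocyte from -0.42 to 0.097, the erythrocyte from -1.78 to 0.13 and the sebaceous from -0.46 to 0.26. A slide or scan block was not run, since there was 1 slide and 1 scan, and neither was normexp on the mean signal. Signal over background limits Cdkn2a, Isl2, Dlx6, Col3a1, Limch1 and Slco5a1, which were not well above background on any array of 1 group.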

Other observations

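Of the tests in this part, the counts over other splits were planned and the others were chosen after the results were seen; so were the genes of this paragraph. Without aged replicate 1, with 2 aged arrays left, part of several lists passed the limma threshold. Lower were 11 of 13 melanocyte, 15 of 26 hair shaft and 5 of 25 Notch and Wnt genes. Of 25 stress keratin and alarmin genes 7 were higher and 1 lower. In this fit only young replicate 1 carried Ddx3y and Eif2s3y transcripts, so the groups were not balanced for them. The fit also leaves out the aged array that stood apart, and with it part of the spread between aged samples. The following fold changes and differences with adjusted p come from the same fit. The melanocortin receptor gene Mc1r was 5.37-fold lower (adjusted p = 0.00327), Mlana 7.01-fold lower (adjusted p = 0.00327) and Lef1, a transcription factor of Wnt signalling, 12.4-fold lower (adjusted p = 0.00611). Krt35 and Krt31, keratins of scale and hair, differed by -5.64 and -4.77 log2 units (adjusted p = 0.00388 and 0.0235). S100a8 and S100a9 were 20.9-fold and 18.6-fold higher (adjusted p = 0.00300 and 0.00327), the protease inhibitor gene Slpi 4.25-fold (adjusted p = 0.0103) and the immediate early gene Fosb 3.91-fold (adjusted p = 0.0374). With all 6 arrays Fosb differed by 1.01 ± 0.82 (limma adjusted p = 0.535). Fosb read 1.38 on aged replicate 1, 4.67 and 3.81 on aged replicates 2 and 3, and 1.79 to 2.63 on the young arrays. The Langerhans cell gene Cd207 had log2 signals of -6.96 on aged replicate 1, -3.90 on aged replicate 2 and -1.83 on aged replicate 3, against -2.43 to -1.64 on the young arrays. Hba-a1, a haemoglobin gene, was at 0.87 and -0.16 on replicate 1 of the young and aged groups and at 3.96 to 5.50 on the others.

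Hair shaft and inner root sheath genes were lower in the aged arrays. The scaling and background settings left a mean shift of -2.49 log2 units or more in size, the one that took most taking 0.21 ± 0.13 (SE between arrays), which argues against them as the cause. Between the 4 arrays without Ddx3y and Eif2s3y transcripts the shift was -3.57 ± 0.96. Within the pair with these transcripts, 1 array of each group, it was -0.98. A difference between the 2 kinds of array that is equal in both groups cancels in aged minus young by design. These values therefore do not test it, and they are too few to tell whether the shift differs between the kinds. Less follicle and gland tissue of every kind was examined with the 14 sebaceous genes that vary by 0.5 or more between the young arrays. Their median was 0.063 (95% interval -0.705 to 0.416) beside a hair list median of -3.32 (-3.66 to -1.42). Without aged replicate 1 it was -0.79 (-1.31 to -0.127) beside -4.61 (-5.06 to -1.88). These intervals run over genes of the same arrays, which are not independent replicates, so they leave out the spread between arrays. The medians show that these sebaceous genes fell less than the hair genes, or not at all, but cannot decide on the cause. Less tissue of every kind stays open. The sebaceous medians on the aged arrays (0.79, 0.20 and -0.85) rank these arrays as the hair medians do (-0.74, -3.05 and -5.88). An order of 3 arrays can match by chance, and on aged replicate 1 the 2 medians had opposite signs. On the young arrays the order differed, with sebaceous medians of 0.31, -0.09 and -0.33 and hair medians of 0.24, -0.35 and 0.12. Without aged replicate 1 the sebaceous genes Dgat2l6 and Mc5r, well above background on every array, were at -1.65 and -1.31 (limma adjusted p = 0.151 and 0.191, neither past the threshold). Awat2, not well above background on any aged array, was then the 1 sebaceous gene of 22 past the threshold, and was lower (limma adjusted p = 0.0106). The outer root sheath list had a median of -0.31 (-0.572 to -0.0473). A change in the hair-forming part alone, such as fewer growing follicles with age, stays open too and was not tested.

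Cell cycle genes were higher in the aged arrays. Scaling and background settings left a mean shift of at least 0.41 log2 units, taking 0.065 ± 0.028 (SE between arrays) at most, which argues against them as the whole cause. Within the 4 arrays without Ddx3y and Eif2s3y transcripts the shift was 0.59 ± 0.13. As each group held 1 array with these transcripts, a difference equal in both groups cancels by design, and this value does not test it. The pair of arrays with these transcripts gave 0.25, but 1 array against 1 decides nothing where the young medians spread from -0.20 to 0.32. The slide row cannot be told apart from the groups: its block gave 0.57, but row 2 held all 3 aged arrays and only young replicate 3. Age itself stays open, as does a deviation shared by these genes on single arrays, since the list's call did not hold with an estimated correlation.

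The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 11 genes and the highest other 1, so 1 of 10 splits gave as many. The looser count was 577 and 417 for the highest other, again 1 of 10 splits. For lists the real count was 8 and the highest other 12, and 4 of 10 splits gave as many. The larger list counts were 9 with young replicates 1 and 2 grouped with aged replicate 1, 12 with young replicates 1 and 3 grouped with it, and 10 with young replicate 1 grouped with aged replicates 2 and 3. Of the 4 splits that part all 3 same-numbered pairs, the others gave 0 genes each (203, 57 and 530 at an unadjusted p under 0.05), 36, 8 and 103 genes by the looser count, and 4, 3 and 10 lists.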
